A study of Drosophila melanogaster with 27 samples.

How the data were processed

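Expression values are those deposited by the authors, on a log2 scale for a 1-colour Affymetrix Drosophila array; per the submitters' processing notes they were computed with GCRMA, whose version is not given in the sources used here. Raw intensity files were not used here. The 24 arrays of RFP-sorted neurons have upper quartiles of log2 3.66 to 4.46. The 3 cyc0 arrays, from GFP-sorted neurons and a later submission, have upper quartiles of 3.09 to 3.18, so they were fitted only in the comparison that needs them.

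The array carries 18869 probe sets, of which 100 are controls. Of the others 13647 name 1 gene, 402 name several and 4820 have no gene name in the annotation used; 11982 genes are named by at least 1 probe set. Control probe sets were left out, and a probe set was tested if its log2 value was above 4 in at least 3 arrays. That left 7333 probe sets over 24 arrays and 7450 over 27. Probe sets without a gene name were tested but are not named in the text. Where several probe sets name a gene, the one with the highest mean over the 24 arrays was used, giving 5377 genes for the gene lists and correlations.

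Linear models with 1 mean per group were fitted in limma 3.58.1 under R 4.3.3, with empirical Bayes moderation of the variances and Benjamini-Hochberg adjustment over all tested probe sets; adjusted p below 0.05 was the threshold. The 8 RFP-sorted groups were fitted together, and all 9 groups for cyc0. Interactions are contrasts of the same fits. The median residual SD was 0.97 log2 with 16 residual degrees of freedom. Genes are named in the text if they belong to a fixed list or are among the largest called differences of a comparison, higher or lower.

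The 31 gene lists were fixed from general knowledge before the data were examined; 520 of their members matched a probe set and 111 did not. Each list was tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the residuals. Members were also adjusted over the list alone. Lists of the 100 genes with the strongest wild-type difference in each direction were tested in the other comparisons. Correlations between comparisons that share a group of arrays were set beside values simulated without any effect. Genes were simulated independently of each other, so these ranges can be narrower than for real, correlated genes.

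In simulated data with the residual spread of these arrays, planted differences of log2 1, 2, 3 and 4 were recovered in 4, 20, 52 and 70 percent of cases for the wild-type time comparison, with 6 of 7133 unplanted probe sets called. For cyc0 the shares were 6, 24, 40 and 74 percent, with 3 of 7250 unplanted called. For the interaction of Kir with time they were 0, 2, 12 and 36 percent, with 3 of 7133 unplanted called. Camera called 20 of 20 moved sets of 100 genes and 1 of 20 unmoved ones. The simulated genes were independent of each other, so this does not test the preset correlation on lists of correlated genes.

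Alternatives were no filter, a stricter filter, quantile normalization of all arrays together, fits of only the groups compared, an intensity trend, array weights, a replicate block, estimated correlations, shorter and longer time lists, and each array left out. Added after the results were seen were the gene lists under quantile normalization and with each array left out, the joint removal of 2 arrays with muscle transcripts, and 2 comparisons of 30 °C with 25 °C. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.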

Results

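Larval LNv pacemaker neurons of Drosophila were sorted in 9 groups of 3 arrays each. In 8 groups, 24 arrays in all, the neurons carried RFP under Pdf control: wild type at circadian times CT3 and CT15, neurons made hyperexcitable by the bacterial sodium channel NaChBac (NCB) at CT15, NCB in a per0 background at CT15, neurons silenced by the inward rectifier Kir2.1 (Kir) at CT3 and CT15, and NCB or its control induced at 30 °C, both at CT15. The ninth group, cyc0 mutants with Kir at CT3, was sorted by GFP. Array medians lay at log2 2.51 to 2.60 in the RFP arrays, with maxima of 12.24 to 12.90 and 22.9 to 27.7 percent of probe sets above log2 4. The GFP arrays had medians of 2.51 to 2.53 but only 17.4 to 18.8 percent above log2 4. Arrays of a group correlated at 0.843 to 0.913, arrays of different groups at 0.754 to 0.920. The p-values of single probe sets come from limma and measure spread between samples labelled biological replicates. Their variance is pooled over all groups fitted. The p-values of gene lists come from camera, which sets the genes of a list against all other genes. They depend on the inter-gene correlation used. Differences against a group near log2 2.2 to 2.9 depend on the floor that GCRMA sets for unexpressed genes.

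Clock transcripts of wild-type LNvs differed between CT3 and CT15 in both directions. tim, Pdp1 and vri were lower at CT3, by log2 −5.61 ± 0.79 (SE; adjusted p = 0.00041), −3.46 ± 0.47 and −1.64 ± 0.39 (adjusted p = 0.033). Clk and cry were higher, by 3.43 ± 0.65 (adjusted p = 0.0047) and 2.73 ± 0.66 (adjusted p = 0.037). tim stood at 12.07 ± 0.17 (SD) at CT15, and its 3 CT3 arrays spread from 3.29 to 8.62. per (−0.91), cwo (−0.53) and cyc (−1.66) did not pass. Thus 5 of 8 clock genes passed, 2 higher and 3 lower, and 6 when adjusted over the list alone, where cyc joined on the strength of 1 CT15 array (6.73, against 3.55 and 3.32 in the others); with members moving both ways the list as a whole had adjusted p = 0.0639 (adjusted p = 0.25 with an estimated correlation). Calls of cry and vri were lost on leaving out any 1 of the 6 arrays.

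**Figure D1:**
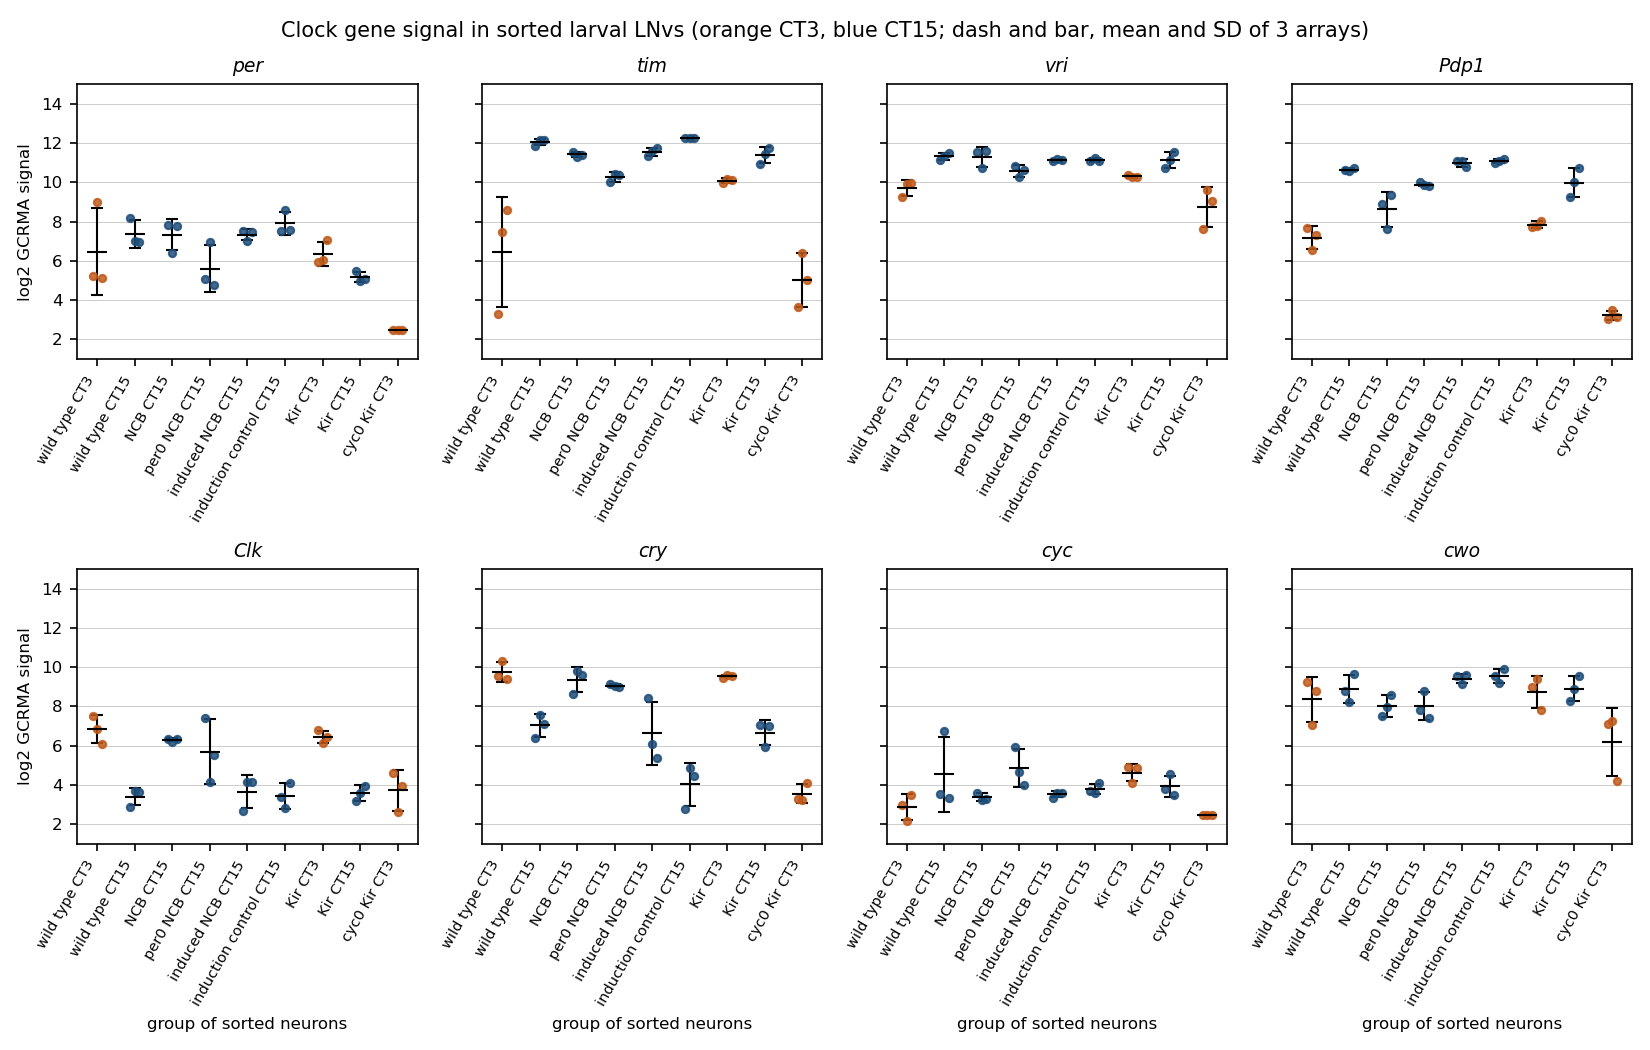
Levels of the 8 clock genes in each group of 3 arrays. tim falls from 12.07 at CT15 to 6.45 at CT3 in wild type.

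Scp2 had the largest wild-type difference by time of day among named genes. Scp2, a calcium-binding protein gene, was at 2.54 at CT3 and 10.71 at CT15, a difference of −8.17 ± 0.91. Pdfr, the PDF receptor (−4.56 ± 0.71), Irk1, an inward rectifier potassium channel (−4.40 ± 0.70), Trpm (−4.93), Pura (−4.71), Dh44 (−4.48) and CadN (−2.37) were also lower at CT3. Higher at CT3 were Nmdmc (5.15), the zinc-finger gene chinmo (5.05 ± 0.65), the kinase gene Dyrk2 (4.87 ± 0.63; 10.16 ± 0.29 against 5.29 ± 1.01, SD), CG10737 (4.70), the sodium/proton exchanger Nhe2 (3.42), Ddc (3.25), the adenylyl cyclase Ac13E (2.84) and the prohormone convertase amon (2.16). Of 11 peptidergic genes amon rose and Pdfr fell; of 13 potassium channel genes only Irk1 passed, and of 10 cAMP genes Ac13E, joined by Epac over the list alone. In limma 119 probe sets passed, 50 higher and 69 lower at CT3, with 818 at unadjusted p below 0.05. Of 30 named genes called, 22 kept the call with every array left out; Dh44 and amon lost it without 5 of the 6 arrays, CadN without 3. The count was 73 without wild-type CT15 replicate 2, and 33 with only the groups compared in the fit.

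NCB at CT15 lowered Scp2 and Pdfr and raised Dyrk2 and CG12994. Scp2 (−7.89), Pdfr (−4.39) and Dh44 (−4.402) fell, while Dyrk2 (4.96), Nmdmc (4.55), Nhe2 (3.33), amon (2.42) and Ac13E (2.402) rose. Beyond these, CG12994 (6.003), VepD (5.89), CG6044 (5.39), the neuronal RNA-binding gene Rbp9 (5.10), Ak1 (4.64), CG8128 (4.54), the peptide gene Dh31 (4.03) and the ecdysone-induced Eip93F (3.45) rose; Vha36-3 (−4.30) and Fkbp14 (−4.26) fell. In the clock list Clk rose by 2.90 (adjusted p = 0.022) and Pdp1 changed by −2.02 (adjusted p = 0.029), and over the list alone cry (2.34) joined; tim (−0.64), vri (−0.03), per (−0.05), cwo (−0.87) and cyc (−1.16) did not pass. Clk lost its call without 4 of the 6 arrays, Pdp1, Dh31 and Dh44 without 5.

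Neurotransmitter receptor genes had lower means as a group in NCB neurons. Of 19 tested, Rdl, a GABA receptor subunit, fell by 3.68 over all probe sets, and 5 fell over the list alone: Rdl, 5-HT1A, 5-HT7, GluClalpha and nAChRalpha5. The list mean was −1.18 and its adjusted p = 0.00071 (adjusted p = 0.063 with an estimated correlation), a call kept with every array left out at the preset correlation; Rdl itself lost its call without 4 arrays. In limma 127 probe sets passed, 58 higher and 69 lower, with 949 at unadjusted p below 0.05. The count was 74 without NCB replicate 1, 65 without NCB replicate 2 and 58 with only the groups compared in the fit; of 28 named genes called, 18 kept the call with every array left out.

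Silencing by Kir lowered activity-regulated transcripts at CT3. Hr38, a nuclear receptor gene induced by neuronal activity, fell by 5.05 ± 0.71, from 9.83 ± 0.61 to 4.78 ± 0.63 (SD). It alone of 13 activity-regulated genes passed over all probe sets; over the list alone CG14024 and puc fell too. The list mean was −1.39, with adjusted p = 5.5e-07 (adjusted p = 0.00064 with an estimated correlation), and the call was kept with every array left out. The cAMP list, in which Epac fell by 2.42, had adjusted p = 0.0216 (adjusted p = 0.085 with an estimated correlation) but lost the call without wild-type CT3 replicate 1 or 2 or Kir CT3 replicate 1. The ER stress list, with none of 13 members past the threshold, also had adjusted p = 0.0216 (adjusted p = 0.0732 with an estimated correlation), and lost the call without wild-type CT3 replicate 1 or Kir CT3 replicate 3. Marker lists of glia, neuroblasts, hemocytes, muscle and other neurons each had adjusted p = 0.96.

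The receptor of short neuropeptide F, sNPF-R, rose by 7.06 ± 1.26 in Kir neurons at CT3, from 3.42 to 10.48. CG3777 (4.77), CG11498 (4.31), beat-IIa (3.63), CG32204 (3.35), the guanylyl cyclase Gyc89Da (3.32) and mtt (3.29) rose as well. CG5023 (−6.85 ± 0.71), fest (−4.67), PVRAP (−4.64), Nmdmc (−4.29) and Nhe2 (−2.58) fell. Of 8 clock genes tim alone passed, at 3.64 ± 0.79 (adjusted p = 0.025), against wild-type arrays that disagree about its level; Clk (−0.37), cry (−0.20), per (−0.13), Pdp1 (0.65) and vri (0.61) did not pass. Calls of tim, CG3777 and Epac were lost without 3 of the 6 arrays, those of mtt and Nhe2 without 5. In limma 71 probe sets passed, 28 higher and 43 lower, with 688 at unadjusted p below 0.05. The count was 46 without wild-type CT3 replicate 2, 43 without Kir CT3 replicate 1 and 34 without Kir CT3 replicate 2, and 24 with only the groups compared in the fit; 14 of 22 named genes kept their call with every array left out. The median difference was 0.109, and 0.009 after quantile normalization.

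At CT15 Kir again lowered activity-regulated transcripts. Hr38 fell by 3.54 ± 0.71 (adjusted p = 0.016), CG8910 fell over the list alone, and the list mean was −1.34, with adjusted p = 1.2e-05 (adjusted p = 0.00203 with an estimated correlation), kept with every array left out. Pdfr (−3.60), the calcium-binding Cbp53E (−4.08), Vha36-3 (−4.52), ND-51L2 (−3.10) and CG5023 (−5.15) fell; CG3777 (5.28), shf (4.86), Tep4 (4.50), the superoxide dismutase Sod3 (4.27), TkR86C (4.19) and Gyc89Da (3.66 ± 0.48) rose. No clock gene passed; per stood at −2.21 (adjusted p = 0.30). Hr38 lost its call without 4 of the 6 arrays and Pdfr without 2.

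Cell-cycle and sodium channel genes gave list-level differences in Kir neurons at CT15, at the preset correlation only. None of 9 cell-cycle genes passed over all probe sets, but CycB3, CycE, dpa, Mcm5, Mcm6 and RnrL rose over the list alone; the list mean was 1.68, with adjusted p = 2.3e-05 (adjusted p = 0.094 with an estimated correlation). The sodium channel list of 9 had a mean of −1.04, with NaCP60E and Teh4 lower over the list alone and adjusted p = 0.00339 (adjusted p = 0.0704 with an estimated correlation); without wild-type CT15 replicate 2 it was 0.0696. The peptidergic list had a mean of −0.61 and adjusted p = 0.0338 (adjusted p = 0.15 with an estimated correlation), lost without wild-type CT15 replicate 1 or 3 or Kir CT15 replicate 1. In limma 55 probe sets passed, 28 higher and 27 lower, with 731 at unadjusted p below 0.05. The count was 24 without wild-type CT15 replicate 2, 35 without replicate 3 and 28 without Kir CT15 replicate 1, and with only the groups compared in the fit no probe set passed (0); 7 of 20 named genes kept their call with every array left out.

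Within Kir neurons several transcripts still differed between CT3 and CT15. Clk (2.89; adjusted p = 0.042) and cry (2.88; adjusted p = 0.045) were higher at CT3 and Pdp1 (−2.16; adjusted p = 0.042) lower, each with calls lost without 5 or 6 of the 6 arrays; tim (−1.29), per (1.18) and vri (−0.82) did not pass. Ccn (4.50), Dyrk2 (3.67), chinmo (3.45), Atf-2 (3.25) and NaCP60E (2.82) were higher at CT3, and Scp2 (−5.07), shf (−4.88), Sod3 (−4.76), the cyclin gene CycB3 (−4.49), CG12880 (−3.77 ± 0.37) and Pvr (−3.11) lower. The cell-cycle list had a mean of −1.83 (adjusted p = 1.8e-07; adjusted p = 0.0654 with an estimated correlation) with CycB3 past the threshold and 6 members lower over the list alone, and the oxidative phosphorylation list of 26 a mean of 0.75 (adjusted p = 0.00027; adjusted p = 0.0654 with an estimated correlation) with none past it. In limma 48 probe sets passed, 26 higher and 22 lower, with 648 at unadjusted p below 0.05. The count was 16, 16 and 29 without Kir CT3 replicates 1, 2 and 3, and 24 and 26 without Kir CT15 replicates 1 and 2. It was 0 with only the groups compared in the fit, 29 with a replicate block and 75 with array weights; 6 of 23 named genes kept their call with every array left out.

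Pdfr, CG15529 and CG12880 differed in how Kir altered them at the 2 times. Pdfr rose from 5.03 at CT3 to 9.58 at CT15 in wild type but stood at 7.18 and 5.98 in Kir neurons, an interaction of 5.75 ± 1.01 (adjusted p = 0.036). CG15529 (2.72 ± 0.48; adjusted p = 0.036) was at 4.94 only in Kir neurons at CT3, and CG12880 (−3.51 ± 0.52; adjusted p = 0.0093) at 6.35 only in Kir neurons at CT15. Limma called these 3 probe sets, 2 higher and 1 lower, and 476 reached unadjusted p below 0.05; quantile normalization gave 2 higher and 5 lower, and a fit of only the groups compared 0. None of the 3 kept its call with every array left out, and a simulated difference of log2 3 was recovered in 12 percent of cases.

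Hyperexcited and silenced neurons at CT15, compared directly and without the wild-type arrays, differed in the largest number of probe sets among RFP groups. Pdf, the neuropeptide gene of these neurons, was higher in NCB than in Kir by 1.87 ± 0.37 (adjusted p = 0.0042), at 12.39 ± 0.22 against 10.52 ± 0.29 (SD). Of 11 peptidergic genes 3 rose, amon (2.27), the amidating lyase Pal2 (1.46) and Pdf, and 7B2 joined over the list alone; the list mean was 0.93, with adjusted p = 0.00196 (adjusted p = 0.0378 with an estimated correlation). Of 13 activity-regulated genes CG17778 (5.07), CG8910 (3.41) and Hr38 (3.22, adjusted p = 0.012) were higher in NCB than in Kir. The list mean was 1.26, with adjusted p = 0.00411 (adjusted p = 0.0378 with an estimated correlation). This list was not called in NCB against wild type at CT15. Hr38 stood at 7.60 in NCB and 7.92 in wild type, against 4.38 in Kir. Of 10 cAMP genes Ac78C (3.64) and Epac (2.51) rose, joined by Pka-C3 and Pka-R1 over the list alone; the mean was 1.27, with adjusted p = 0.00196 (adjusted p = 0.0378 with an estimated correlation). These 3 list calls were kept at the preset correlation with every array left out, but at the estimated one they reached 0.0909, 0.0909 and 0.0698. There the peptidergic call was lost without NCB replicate 1, 2 or 3 or Kir CT15 replicate 2, the activity-regulated call without NCB replicate 1 or 2 or Kir CT15 replicate 2, and the cAMP call without NCB replicate 1 or 3 or Kir CT15 replicate 2.

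The receptor genes Rdl, nAChRalpha2 and 5-HT7 and the replication gene Mcm5 were lower in NCB than in Kir. Rdl (−3.58), nAChRalpha2 (−4.25) and the serotonin receptor 5-HT7 (−4.41) fell; the receptor list mean was −1.003, with adjusted p = 0.00782 (adjusted p = 0.0938 with an estimated correlation), lost without NCB replicate 2 (0.0541) or Kir CT15 replicate 2 (0.106). Mcm5 (−2.43) fell in the cell-cycle list, whose mean was −1.62 (adjusted p = 0.00063; adjusted p = 0.0938 with an estimated correlation). Ribosomal protein genes had a mean of −0.42 (adjusted p = 0.00411; adjusted p = 0.586 with an estimated correlation), lost without Kir CT15 replicate 1. Synaptic vesicle genes (adjusted p = 0.0351) and ER stress genes (adjusted p = 0.0463) were higher as lists with no member past the threshold, and at the estimated correlation had adjusted p = 0.236 and 0.0938. The synaptic call was lost without NCB replicate 1 or 2 or Kir CT15 replicate 1, the ER stress call without any array but NCB replicate 1. Scp2 (−7.41), sNPF-R (−7.09), Fkbp14 (−6.61), CG32204 (−5.66), beat-IIa (−5.61), mtt (−5.49), Gyc89Da (−5.43), TkR86C (−4.96) and Sod3 (−4.71) fell. Dyrk2 (6.40 ± 0.63), CG12994 (6.02), VepD (5.87), PVRAP (5.78), orb (5.52), Cbp53E (5.43), bnb (5.16), Nhe2 (4.60), Dh31 (4.21), Clk (2.73; adjusted p = 0.020), NaCP60E (2.71) and cry (2.70; adjusted p = 0.026) rose. per (2.16; adjusted p = 0.18) and Pdp1 (−1.37; adjusted p = 0.14) did not pass. In limma 220 probe sets passed, 123 higher and 97 lower, with 1053 at unadjusted p below 0.05, and 145 without NCB replicate 1 or without NCB replicate 2. Of 39 named genes called 26 kept the call with every array left out; Clk lost it without 5 arrays, cry without 3, Hr38 without 2.

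**Figure D2:**
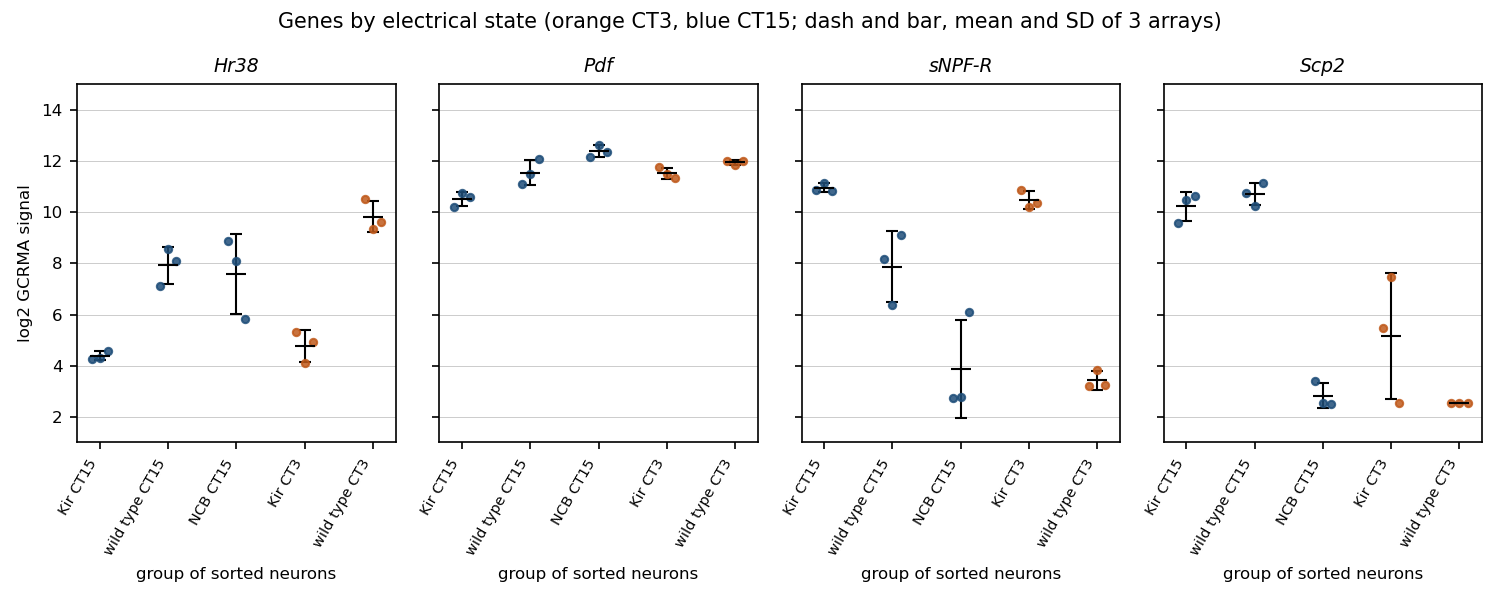
Genes that differ between hyperexcited and silenced neurons at CT15, shown in wild type and Kir at both times and in NCB at CT15. Pdf is at 12.39 in NCB and 10.52 in Kir.

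Genes higher at CT3 in wild type, such as Dyrk2, Nhe2 and Clk, were mostly higher in NCB than in Kir neurons at CT15. Of the 100 genes most strongly higher at CT3, 79 were higher in NCB, 35 of them past the threshold (mean 1.52; p = 2.8e-22, and 4.8e-10 with an estimated correlation). Of the 100 most strongly higher at CT15, Scp2 among them, 68 were lower in NCB, 13 past the threshold and 1 higher past it. Their mean was −0.89 (camera p = 6.7e-08, and 0.00505 with an estimated correlation). Against the wild-type CT15 arrays, which also defined the lists, Kir gave means of 0.12 and −1.04 and NCB 1.64 and −1.92. The CT15 genes were thus lower in both, a direction the shared arrays favour. No opposite movement of Kir and NCB from wild type is shown. Within Kir neurons, from CT15 to CT3, 81 of the CT3 genes were higher (mean 1.14) and 64 of the CT15 genes lower (mean −0.52; p = 0.00506 with an estimated correlation; mean −0.82 without Kir CT15 replicate 1). Across 5377 genes the wild-type time difference correlated with NCB against Kir at 0.217, where simulation without effects gave −0.0418 to 0.0381. The simulated genes were independent, so this range can be too narrow and does not measure chance. In this pair of comparisons 18 genes were called higher in both against 0.676 expected, and 8 lower in both against 0.572. Cipc alone went opposite ways. The expected counts take calls as independent, but both comparisons use the same pooled variance of each gene. The excess therefore does not measure agreement alone, here or for the other expected counts. The wild-type time difference correlated with time in Kir at 0.198, with 7 and 4 shared calls against 0.134 and 0.114 expected. Dyrk2, chinmo and Scp2 were among these shared calls.

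**Figure D3:**
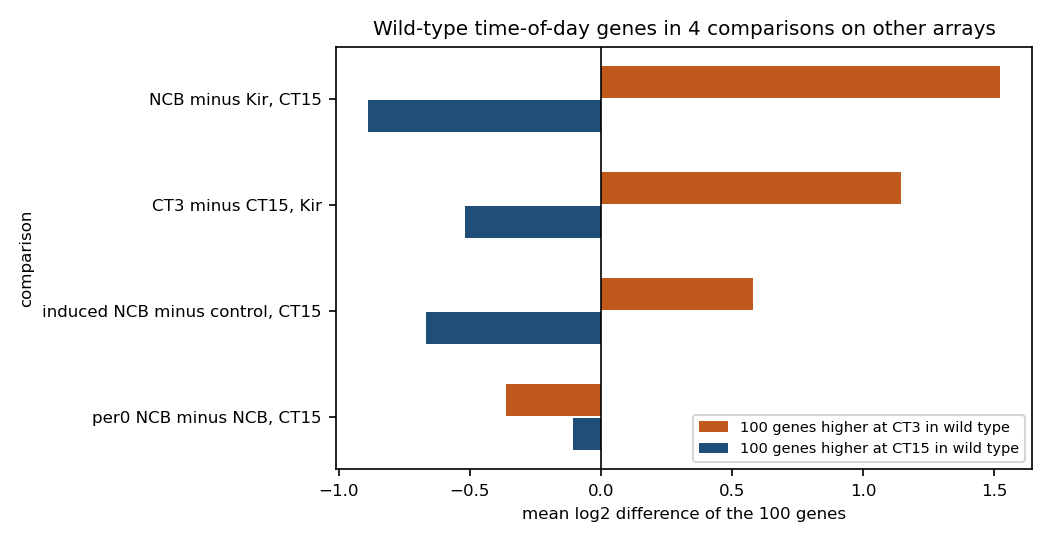
Mean differences of the 100 genes higher at CT3 and the 100 higher at CT15 in wild type, in the other comparisons. The means are 1.52 and −0.89 in NCB against Kir.

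For comparisons with a wild-type group in common, most of the correlation comes from the shared arrays. The simulated ranges take genes as independent, so a place within or below a range is not a test. Wild-type time and NCB at CT15 correlated at 0.541, within the simulated range of 0.464 to 0.542 (mean 0.5003); the covariance beyond the shared part was 0.265, and 18 genes were called higher and 18 lower in both, Nhe2 and Scp2 among them. The 0.335 and 0.267 expected take the calls as independent, which calls against the same CT15 arrays are not, so the excess is no measure of agreement. Wild-type time and Kir at CT3 correlated at −0.523, within the simulated range of −0.525 to −0.470 (mean −0.498, covariance difference −0.183). The 22 genes called in both, such as tim and Nmdmc, went in opposite directions. NCB and Kir at CT15 correlated at 0.362, below the simulated range of 0.464 to 0.521 (mean 0.498, covariance difference 0.0391), with 1 gene higher and 6 lower in both, Pdfr and Vha36-3 among the latter, and 1, bnb, in opposite directions. Kir at CT3 and at CT15, which share no arrays, correlated at 0.188, with 5 genes such as Gyc89Da higher and 6 such as Hr38 lower in both, against 0.0855 and 0.106 expected.

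NCB induced at 30 °C changed amon, Eip93F, Rbp9, VepD and Vha36-3, which constant NCB changed in the same directions. amon rose by 2.90 ± 0.51 (adjusted p = 0.0058), Eip93F by 4.18, Rbp9 by 4.11 and VepD by 3.83; CG6738 (4.81), tra (4.01), CG14995 (3.998), c-cup (3.71) and Rpn7 (2.93) rose as well. E(spl)m6-BFM (−4.90), CG32204 (−4.62), Vha36-3 (−4.50), NK7.1 (−4.06) and ND-18 (−3.99) fell. No clock gene passed, with cry at 2.59 (adjusted p = 0.059). Of the genes higher at CT3 in wild type 71 of 100 were higher (mean 0.58; p = 8.2e-05), and of those higher at CT15 66 of 100 were lower (mean −0.67; p = 1.0e-07, and 0.00558 with an estimated correlation). No fixed list passed under camera; the receptor list had adjusted p = 0.111, with 4 members lower over the list alone. In limma 95 probe sets passed, 55 higher and 40 lower, with 913 at unadjusted p below 0.05. The count was 63 and 58 without induced NCB replicates 1 and 3 and 56 without its control's replicate 3, 39 with array weights and 0 with only the groups compared in the fit; amon was among the 13 of 22 named genes that kept their call with every array left out.

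Constant and induced NCB correlated at 0.208 across genes without sharing arrays, with 12 genes higher in both, amon and Eip93F among them, and 6 lower in both, against 0.409 and 0.195 expected. Wild-type time correlated with induced NCB at 0.106, with 4 and 5 genes called in both against 0.295 and 0.229 expected. Only E(spl)m6-BFM (4.71 ± 0.78; adjusted p = 0.022) and CG8128 (4.29 ± 0.65; adjusted p = 0.011) were called as different between constant and induced NCB effects. Both also differ between the 2 wild-type controls, by 4.72 and 4.13. So does ND-18, by 5.26 (adjusted p = 0.0067), while it stood at 0.30 between induced and constant NCB, so its fall with induced NCB goes with a raised control. Limma called these 2 probe sets, with 654 at unadjusted p below 0.05 and 0 with only the groups compared in the fit. Neither kept its call with every array left out. In the interaction of Kir with time a simulated difference of log2 3 was recovered in 12 percent of cases, so few calls do not show equal effects. The wild-type CT3 and CT15 genes had means of 1.06 and −1.26 in this contrast, which shares the wild-type CT15 arrays with the lists.

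Loss of per in NCB neurons lowered CG12994, the call that held best. CG34187 (3.37), rogdi (3.28) and the respiratory-chain gene COX7B (3.20) rose; CG12994 (−4.31), BEAF-32 (−4.09), Drep1 (−3.86), chinmo (−3.64) and DIP-gamma (−3.54) fell. No clock gene passed, with per at −1.72 (adjusted p = 0.46), tim at −1.15 and Pdp1 at 1.26; per0 is a nonsense allele, so its transcript level does not test the genotype. The oxidative phosphorylation list had a mean of 0.65 and adjusted p = 0.00092 (adjusted p = 0.159 with an estimated correlation). The ribosomal protein list had a mean of 0.37 and adjusted p = 0.00591 (adjusted p = 0.931 with an estimated correlation), lost without NCB replicate 1 or per0 replicate 3. Of the genes higher at CT3 in wild type 70 of 100 were lower (mean −0.36; camera p = 0.00632, and 0.00189 with an estimated correlation), while those higher at CT15 had a mean of −0.11 (p = 0.621). In limma 22 probe sets passed, 13 higher and 9 lower, with 765 at unadjusted p below 0.05. The count was 11 without NCB replicate 1 or replicate 2, and 8, 4 and 41 without per0 replicates 1, 2 and 3, and 0 with only the groups compared in the fit; of 12 named genes only CG12994 kept its call with every array left out. The muscle genes Mlc1 (6.71 and 9.56), Mlc2 (8.93 and 7.45) and bt (8.09 and 6.02) were high in per0 replicates 1 and 2. They were not in replicate 3 (2.55, 3.61 and 2.42), and the muscle list had adjusted p = 0.704. Replicate 3 held the fat body transcripts Fbp1 (7.63), Lsp2 (6.15) and Fbp2 (5.17), and Lsp2 was at 7.36 in replicate 1. NCB replicate 1 held Mlp84B (7.51) and Mlc1 (6.23), so transcripts of other tissues occur in both groups.

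Scp2, Irk1 and the GABA receptor subunit Rdl were lower in per0 NCB neurons than in wild type at CT15. Scp2 fell by 8.17, hig by 5.54, CG5023 by 5.12, Irk1 by 4.09, Rdl by 3.72, CG14024 by 3.57 and CadN by 2.03. VepD (6.14), Rbp9 (5.30), Ak1 (4.51), Eip93F (4.23), Dyrk2 (4.20), Tbh (3.74), Pal1 (3.09), Ac13E (2.66) and Nhe2 (2.55) rose. Clk (2.29; adjusted p = 0.079), cry (2.04), tim (−1.79) and per (−1.77) did not pass. Receptors had a mean of −1.44 and the oxidative phosphorylation genes of 0.84, each with adjusted p = 0.00015 (adjusted p = 0.0431 with an estimated correlation). At the estimated correlation both list calls were lost without wild-type CT15 replicate 1 or 2 or per0 replicate 1 or 2, with adjusted p up to 0.117. In limma 140 probe sets passed, 67 higher and 73 lower, with 1009 at unadjusted p below 0.05, and 75 and 81 without per0 replicates 1 and 2, and 78 with only the groups compared in the fit. These 2 arrays hold the muscle transcripts, such as Mlc1 (6.71 and 9.56). The oxidative phosphorylation mean was 0.85, 0.80 and 0.87 without per0 replicates 1, 2 and 3, so it did not go with the muscle transcripts. Only replicate 3 lacks these, and it holds fat body transcripts such as Fbp1 (7.63), so RNA of other tissues is not excluded. Of 30 named genes called 17 kept the call with every array left out.

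All 8 clock genes were lower in cyc0 Kir neurons than in Kir neurons at CT3. cry fell by 6.02, tim by 5.07, Pdp1 by 4.62, per by 3.89, Clk by 2.74, cwo by 2.55, cyc by 2.18 and vri by 1.56; the list mean was −3.58, with adjusted p = 3.2e-07 (adjusted p = 0.00038 with an estimated correlation). After quantile normalization tim (−3.90), Pdp1 (−3.60), per (−3.63) and cry (−4.90) still passed, while Clk (−1.76), cyc (−1.77), cwo (−1.38) and vri (−0.68) did not. Pdf fell by 5.42 ± 0.42, from 11.53 ± 0.22 to 6.11 ± 0.94 (SD), and Pdfr by 4.37; quantile normalization gave −4.33 and −3.81. ana (−6.18), CG32052 (−6.25) and Ac13E (−4.21) fell, and Pde1c (4.05), Cyp4p1 (4.005), CAP (3.68), ct (2.92) and miple1 (2.89) rose.

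Oxidative phosphorylation genes were lower as a group in cyc0 Kir neurons, 21 of 26 past the threshold and 23 over the list alone. Their mean was −1.99, with adjusted p = 6.5e-07 (adjusted p = 0.00795 with an estimated correlation). After quantile normalization the mean was −0.99, with adjusted p = 0.00036 but adjusted p = 0.151 with an estimated correlation. Of 8 heat shock genes 4 fell (adjusted p = 0.00432; adjusted p = 0.144 with an estimated correlation). Of 29 ribosomal protein genes 8 fell and of 27 proteasome genes 11, each list with adjusted p = 0.0225 (adjusted p = 0.52 and 0.144 with an estimated correlation), and neither passed after quantile normalization. The ribosomal call was lost without Kir CT3 replicate 1 or cyc0 replicate 2, the proteasome call without Kir CT3 replicate 1 or 3 or cyc0 replicate 1 or 2. The 4 fat body markers had a mean of 0.88 with none past the threshold (adjusted p = 0.00404; adjusted p = 0.0625 with an estimated correlation), and adjusted p = 0.141 after quantile normalization; the mean was 1.34 without cyc0 replicate 2, and without cyc0 replicate 1 too few members remained to test. The 5 muscle markers had a mean of 1.78 (adjusted p = 6.4e-05; adjusted p = 0.138 with an estimated correlation), carried by 1 array: Act87E (8.59), Mlc2 (9.26) and bt (9.14) were high in cyc0 replicate 2, and without it the mean was −0.15 (adjusted p = 0.302). In limma 1252 probe sets passed, 36 higher and 1216 lower, with 2475 at unadjusted p below 0.05. Quantile normalization gave 188 higher and 169 lower, 205 of them shared, and moved the median difference from −0.98 to −0.11. The count was 802, 757 and 770 without Kir CT3 replicates 1, 2 and 3, and 803, 668 and 801 without cyc0 replicates 1, 2 and 3; 50 of 85 named genes kept their call with every array left out.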

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

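The explanations weighed in this part, and the criteria for them, were chosen after the results were seen. Fixed before were the splits of the samples, the list tests of the interactions, and quantile normalization of the counts and time lists. The genes higher at CT3 in wild type lie above those higher at CT15 by a gap of 2.41 log2 (mean difference) in NCB against Kir. Quantile normalization leaves the gap at 2.44 against 2.41 (jackknife 0.24). A shift between arrays cancels in such a gap, and the median difference was already 0.008 as deposited. Little change could therefore arise, so other effects of the processing stay undecided. Members with a mean of at least 6, 48 and 40 of them, give 2.95 (jackknife 0.19), so the gap is not confined to members with a low mean. A high mean does not keep both groups above the floor of GCRMA, however. Scp2 was at 3.40, 2.55 and 2.52 in the NCB arrays and at 9.59, 10.46 and 10.64 in the Kir arrays at CT15. The part of the floor in the gap therefore stays undecided. Induced NCB, with its own control and without Kir arrays, gives 1.25 (larger camera p of the 2 lists 0.00558 with an estimated correlation). A gap of the same sign thus arises without Kir arrays. It is smaller than 2.41 and does not measure RNA of other cells in the Kir arrays, whose part stays undecided. Electrical state and genetic background both remain open, since NCB and Kir neurons carry different transgenes.

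In cyc0 97.1 percent of the called probe sets are lower, and 47.3 percent after quantile normalization, a share that centring brings near even whatever the cause, so the origin of the one-sidedness stays open. The clock list keeps a mean of −2.70 after quantile normalization against −3.58 (p = 1.34e-05 with an estimated correlation), which a shift of all probe sets does not account for. Fewer LNvs in the sort would raise markers of other cells. After quantile normalization all 6 marker lists had positive means, from 0.03 (hemocyte) to 2.30 (muscle). Only muscle passed (adjusted p = 0.029, but 0.479 with an estimated correlation). Without cyc0 replicate 2 the muscle mean as deposited is −0.15. The lists hold only 3 to 9 members, and Pdf, the neuropeptide gene of LNvs, stood at −4.33 after quantile normalization. The explanation by fewer LNvs is therefore undecided. The GFP sort and the background differ along with cyc0 and could produce any part of the difference.

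The cell-cycle list in Kir neurons at CT15 passes at the preset correlation with each array left out (largest adjusted p = 0.00753; mean 1.16 to 2.33) and after quantile normalization (mean 1.89, adjusted p = 0.00064; change 0.22, jackknife 0.37), so neither 1 array nor scaling makes up the difference. With an estimated correlation it does not pass with all arrays (adjusted p = 0.094), after quantile normalization (0.095) or in 4 of 6 fits without an array (up to 0.281), so the list call itself rests on the preset correlation. Neuroblast RNA in the Kir arrays is undecided: the 3 neuroblast markers have a median of −0.10 (adjusted p = 0.992).

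Splitting the samples of a comparison anew gives only 10 splits of 3 against 3, too few for a share under 0.05. The real split gave the highest count, 1 of 10, each time: 119 against at most 7 for wild-type time, 127 against 4 for NCB, 71 against 4 and 55 against 6 for Kir at CT3 and CT15, 48 against 4 for time in Kir, 95 against 5 for induced NCB, 22 against 7 for per0 in NCB, 140 against 4 for per0 NCB against wild type, 220 against 5 for NCB against Kir and 1252 against 2 for cyc0. Without its sign, the gap between the time lists was 2.41 against 1.11 for NCB against Kir and 1.25 against 0.588 for induced NCB. It was 1.66 against 0.938 for time in Kir and 0.255 against 0.246 for per0 in NCB. The per0 gap is reversed, with a mean of −0.36 for the CT3 genes and −0.11 for the CT15 genes.

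Pdfr, at 5.75 in the interaction of Kir with time, CG15529 at 2.72 and CG12880 at −3.51 come from a contrast in which 17 of 100 splits gave at least as many calls as the real 3 (highest 130, in a split that turned the labels of 1 pair, otherwise 22). E(spl)m6-BFM (4.71) and CG8128 (4.29) come from one in which 25 of 100 splits gave at least 2 (highest 30). Splits that turn labels within a pair can carry the Kir or NCB difference itself into the interaction. The shares of 17 and 25 of 100 therefore do not tell whether the calls arise by chance. In the interaction of Kir with time the clock list had a mean of 1.36 (adjusted p = 0.0199; adjusted p = 0.118 with an estimated correlation), lost without wild-type CT15 replicate 2 or Kir CT15 replicate 1. The sodium channel list had 1.32 (adjusted p = 0.0137; adjusted p = 0.118 with an estimated correlation), with NaCP60E, Teh4 and unc80 past the threshold over the list alone, lost without wild-type CT15 replicate 2. The cell-cycle list had −1.89 (adjusted p = 0.00012; adjusted p = 0.12 with an estimated correlation), at most 0.0157 with an array left out.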

How the results depend on the processing

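With each array left out in turn the count of probe sets past the threshold ran from 73 to 101 for wild-type time of day, 65 to 122 for NCB, 34 to 61 for Kir at CT3, 24 to 62 for Kir at CT15, 16 to 43 for time in Kir, 56 to 91 for induced NCB, 4 to 41 for per0 in NCB, 75 to 134 for per0 NCB against wild type, 145 to 199 for NCB against Kir and 668 to 803 for cyc0. The interactions ran from 0 to 8 for Kir by time and 0 to 4 for constant against induced NCB. The means of the wild-type CT3 and CT15 genes ran from 1.49 to 1.63 and −1.10 to −0.71 in NCB against Kir, 1.11 to 1.19 and −0.82 to −0.41 for time in Kir, 0.57 to 0.69 and −0.76 to −0.59 for induced NCB, and −0.41 to −0.25 and −0.17 to 0.01 for per0 in NCB.

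Fitting only the groups compared gave 33 for wild-type time, 58 for NCB, 24 for Kir at CT3, 78 for per0 NCB against wild type, and 0 for Kir at CT15, time in Kir, induced NCB, per0 in NCB and both interactions. Array weights gave 75 for time in Kir, 39 for induced NCB, 1957 for cyc0, 12 for Kir by time and 1 for constant against induced NCB. The stricter filter gave 7 for per0 in NCB and 0 for Kir by time, and the intensity trend 0 for constant against induced NCB. For cyc0 no filter gave 4879 (2703 higher, 2176 lower) and quantile normalization 357; for Kir by time quantile normalization gave 7.

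A block for equal replicate numbers gave 29 for time in Kir, and residuals of equally numbered arrays correlated at a mean of −0.0003 (−0.0764 to 0.0625), so the numbers do not pair the arrays. Of 32 list calls 9 remained with an estimated correlation, and 70 were made without the filter. By Spearman the correlations of wild-type time with NCB against Kir and with induced NCB were 0.146 and 0.0622, that of NCB with induced NCB 0.161 and that of Kir at CT3 with Kir at CT15 0.145; the stricter filter gave 0.249 and 0.227 for the last 2. Without the per0 NCB replicates 1 and 2, an alternative added after the muscle transcripts were seen, per0 in NCB gave 0 and per0 NCB against wild type 2; 1 per0 array then remains and other groups supply the spread, so the loss of replication alone lowers both. In cyc0 the muscle markers had a mean of 1.78, and −0.15, 2.69 and 2.70 without cyc0 replicates 2, 1 and 3.

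Named genes kept their call in 257 of 316 cases without the filter, 289 of 294 with the stricter one, 251 of 314 after quantile normalization, 173 of 314 with only the groups compared, 307 of 316 with an intensity trend, 306 of 316 with array weights, 289 of 316 with the block and 1345 of 1905 with an array left out; none reversed.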

Other observations

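The group means of Pdf and sNPF-R at CT15 lie in an order of electrical state, but only the difference between Kir and NCB passed. Pdf has means of 10.52 in Kir, 11.56 in wild type and 12.39 in NCB; against wild type Kir gave −1.03 (adjusted p = 0.29) and NCB 0.84 (adjusted p = 0.33), the wild-type arrays span 11.09 to 12.07, and the 30 °C control stands at 12.29. sNPF-R has means of 10.95, 7.88 and 3.87, with wild-type arrays from 6.37 to 9.11 and adjusted p = 0.38 for Kir and 0.13 for NCB. Scp2 is at 10.23 in Kir and 10.71 in wild type but at 2.82 in NCB, close to its wild-type CT3 level of 2.54, and at 8.17 with induced NCB. Hr38 is at 9.83 and 7.92 in wild type at CT3 and CT15, at a mean of 7.60 in NCB with arrays at 8.86, 8.09 and 5.84, and at 4.78 and 4.38 in Kir, so the silenced neurons are low at both times. A fuller test of a graded relation needs wild-type, NCB and Kir neurons of 1 background at both times.

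At 30 °C sr and cry differed from 25 °C in both genotypes. sr was higher at 30 °C by 2.996 (adjusted p = 0.0207) in the control and by 2.79 (adjusted p = 0.0229) with NCB, and Hr38 stood at 2.13 (adjusted p = 0.163) and 1.58 (adjusted p = 0.291). cry fell by 2.997 (adjusted p = 0.0319) and 2.74 (adjusted p = 0.0366), at 0.0520 and 0.0549 after quantile normalization, while Clk stood at 0.03 in the control and fell by 2.65 with NCB (adjusted p = 0.0398; 0.0838 after quantile normalization); the clock list had adjusted p = 0.98 and 0.941. The ribosomal protein list had a mean of 0.88 in both (adjusted p = 1.7e-12 and 6.3e-12; 0.169 and 0.255 with an estimated correlation). In the control the oxidative phosphorylation list had a mean of 0.74 (adjusted p = 3.5e-05; adjusted p = 0.0647 with an estimated correlation) and ecdysone genes a mean of −1.09 (adjusted p = 0.0273; adjusted p = 0.169 with an estimated correlation). Limma called 63 probe sets in the control, 22 higher and 41 lower, with 998 at unadjusted p below 0.05, and 134 with NCB, 47 higher and 87 lower, with 1115; 15 were shared in direction. The medians were −0.15 and −0.12, and −0.01 in both after quantile normalization, which called 71 and 108.

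These 30 °C comparisons and the tests on them were chosen after the results were seen. If warmth raised activity in LNvs, the activity-regulated list would rise at 30 °C in both genotypes; it did in the control (adjusted p = 0.0247; adjusted p = 0.0872 with an estimated correlation) and not with NCB (adjusted p = 0.169), which leaves the idea undecided. The real split gave 63 calls in the control against at most 10, and 134 with NCB against at most 2, each 1 of 10 splits. Temperature comes together with the Gal80ts transgene in these groups, so either could be behind the differences.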
